A study of Mus musculus with 6 samples.

How the data were processed

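RNA from the colon of 6 male BALB/c mice was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per mouse, with 4 wild-type (WT, Mthfd1S+/+) and 2 heterozygous (Mthfd1S+/-) animals. Per the labels' protocols, the mice had been backcrossed for at least 10 generations and received azoxymethane (AOM, a colon carcinogen) at 6 mg/kg into the peritoneal cavity. Then came 2 cycles of 4 days with 3% dextran sulfate sodium (DSS, which injures the colonic epithelium), at weeks 1 and 4 after the injection. Animals were killed in week 13, and total RNA was isolated from frozen tissue with a column kit and DNase digestion. The age field of the labels gives 7 months, while the protocol gives 3 months at the injection. The labels call the arrays biological replicates with a mouse identifier each, so the spread between arrays includes the spread between animals.

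The deposited table holds log2 values, 1 per transcript cluster (the array's unit for a gene) and array, summarised by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation algorithm, the background correction and the genome build are not given in the sources used here. The log2 scale was judged from the values, which run from 1.06 to 13.5 and would exceed the range of a 16-bit scanner on another log base. Detection calls were not used here, so a low value cannot be told from background. Any change that the authors' between-array normalization removed from all genes at once cannot be seen in these values.

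The table holds 41345 clusters. The platform table gave exactly 1 gene symbol for 23521 of them, which were tested and cover 22180 symbols. Another 1814 clusters had several symbols and 16010 had none; these were left out of the main tests and no gene was named from them. Through their gene identifiers, 23328 of the tested clusters matched the RefSeq gene table of the assembly GRCm38.p6, and 0 symbols needed an update. That table served for names and for which genes neighbour each other. All columns of the table belong to the 6 arrays.

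Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with 4 residual and 4.35 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all tested clusters with a threshold of 0.05. A descriptive count was set beside it of clusters at an unadjusted p under 0.05 that differed by at least 1.5-fold. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.106. For single values an exact two-sided permutation test was used; the 15 ways to split 6 arrays into 4 and 2 allow no p below 0.0667.

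Before the data were examined, 44 gene lists with 917 genes were fixed, covering folate and one-carbon metabolism, nucleotide and lipid metabolism, DNA damage and repair, inflammation, stem cells, proliferation and stress, and markers of the cell types that colonic mucosa can hold. A gene on several clusters was represented by the one with the highest mean. In all 806 list genes were measured, and 43 lists had at least 5 measured members; the red blood cell list had fewer and was not tested. Of 41 list genes with several clusters, 11 had clusters of opposite sign, and for 0 of these was each sign at an unadjusted p under 0.05. Lists were tested with camera from limma (preset inter-gene correlation 0.01, Benjamini-Hochberg over lists), which asks whether a list's genes stand apart from the other genes. Camera with an estimated correlation and fry were run beside it. Directions of a list are given as Mthfd1S+/- minus WT.

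The rule for naming genes was also fixed then. It takes Mthfd1 and, per direction, the 15 clusters past the adjusted threshold with the largest changes. Places left open went to the smallest unadjusted p among clusters at least 1.5-fold apart whose groups did not overlap. Predicted genes, small RNA genes, olfactory and vomeronasal receptors and single receptor segments were counted but not named. In each list up to 4 members with the smallest p could be named, and in the folate list all members. Genes named outside this rule are said to be so.

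The steps were tested on simulated data: 23521 clusters, of which 200 were changed, in 20 data sets. Values were drawn independently for each cluster, with the moderated spread of these arrays. Of 2-fold changes 98.65% were recovered at the adjusted threshold, and of 4-fold changes 100%, with a mean of 13.2 false calls. With no change the mean was 0.2 calls, and 26.35 clusters passed the descriptive count. Other splits of the real arrays into 4 and 2 gave 17 to 152 clusters in that count. The moderated spread need not match the real spread of each cluster, and real clusters are not independent. The 26.35 is thus no chance level for real clusters, and the recovered shares hold only for such simulated data. A list shifted by 0.25 on the log2 scale was called by camera in 100% of data sets. When members of a list were given correlated values and no change, camera called a mean of 8.72 lists over 100 data sets, and at least 11 in 26 of them.

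Alternatives fixed beforehand were other variance moderation, normalizing again, leaving out the dimmest clusters, testing all rows, array weights, the replicate number as a block, the letter of the mouse identifier as a covariate, other fold thresholds, other list tests, the other cluster of a gene, and leaving out each array. Models with the smooth muscle mean or the mean of a block of unnamed rows as a covariate were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.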

Results

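The data compare colonic mucosa that looked normal, taken beside tumours, from 4 WT and 2 Mthfd1S+/- male mice after AOM and DSS. Mthfd1 encodes a cytosolic folate enzyme whose synthetase activity joins formate to tetrahydrofolate for purine synthesis, and Mthfd1S+/- mice are deficient in that activity. The comparison asks which transcripts of the mucosa differ with the synthetase deficiency. The arrays were alike in overall level, with medians of 5.485 to 5.532 on the log2 scale. Correlations across clusters were 0.993 to 0.995 between WT arrays, 0.993 between the Mthfd1S+/- arrays and 0.991 to 0.994 across genotypes; clusters are not independent replicates.

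The targeted gene's own cluster (Mthfd1, transcript cluster 17276520) stood at 7.63 ± 0.10 (SD, n = 4) in WT and 7.79 ± 0.23 (SD, n = 2) in Mthfd1S+/- mucosa. Single WT mice read 7.64, 7.63, 7.496 and 7.75, and the Mthfd1S+/- mice 7.96 and 7.63. The log2 difference was 0.17 (95% interval -0.10 to 0.43), with an adjusted p of 0.890 in limma and an exact permutation p of 0.4. Without the second Mthfd1S+/- mouse the difference was 0.33, and without the first it was 0.0024. The labels do not say what the allele does to the transcript, so this level does not check the genotypes.

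Among the clusters at least 1.5-fold apart whose groups did not overlap was Zbtb16, a zinc finger transcription factor, at 6.46 ± 0.18 (SD, n = 4) in WT and 7.17 ± 0.13 (SD, n = 2) in Mthfd1S+/- mucosa. Pdk4, a kinase that restrains pyruvate dehydrogenase, stood at 6.19 ± 0.13 and 6.80 ± 0.34 in the same order. On the other side, Ptk6, a tyrosine kinase of epithelia, stood at 7.55 ± 0.17 in WT and 6.88 ± 0.024 in Mthfd1S+/- mucosa. Oas1g, of the interferon-induced oligoadenylate synthetases, stood at 9.33 ± 0.38 and 8.60 ± 0.074. None of the 23521 clusters passed the adjusted threshold in limma, where the smallest adjusted p was 0.837, and none did with unmoderated least squares. At an unadjusted p under 0.05 there were 1363 clusters (790 higher and 573 lower in Mthfd1S+/-), where chance gives 1176 on average. Clusters that move together widen the spread around that number. Other splits of the 6 arrays into 4 and 2 gave 704 to 2523 clusters at that threshold. Of the 1363, 79 were at least 1.5-fold apart, 35 higher and 44 lower, and 4 were at least 2-fold apart. The groups did not overlap in 14.0% of clusters, where chance gives 13.3%. With each array centred on its median, 77 clusters were at least 1.5-fold apart, 25 of them higher. The count was 153 without WT mouse 4, 340 without the first and 159 without the second Mthfd1S+/- mouse.

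Of the 15 named genes higher in Mthfd1S+/- mucosa, the calmodulin regulator Pcp4 had a log2 fold change of 0.71 ± 0.14 (SE), and the X-linked proteoglycan Gpc3 of 0.87 ± 0.20. The cholecystokinin receptor Cckar had 0.68 ± 0.18, the calcium binder Scgn 0.64 ± 0.20 and Dbh, which makes noradrenaline, 0.59 ± 0.20. Scube2 had 0.65 ± 0.14, Fam155a 0.77 ± 0.24 and Elmod1 0.60 ± 0.18. Nxpe2 had the largest value, 0.97 ± 0.31, or 1.96-fold. The carboxylesterase Ces2a had 0.71 ± 0.20 and the small GTPase Rasl11b 0.61 ± 0.12. The metallothionein Mt4 (0.65 ± 0.10) and the zinc finger gene Zfp874b (0.63 ± 0.14) lay in the dimmest part of the tested clusters, below a mean of 5.12. For all of these the adjusted p was 0.837. Without the second Mthfd1S+/- mouse, the values were 0.55 for Nxpe2, 0.42 for Fam155a, 0.36 for Elmod1, 0.45 for Pcp4 and 0.37 for Pdk4.

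Of the 15 named genes lower in Mthfd1S+/- mucosa, Xaf1 and Ifi27l2b belong with Oas1g to interferon-induced families, with log2 fold changes of -0.61 ± 0.18 (SE) and -0.62 ± 0.13. The immediate early gene Fos had -0.63 ± 0.20 and the phospholipase gene Pla2g4f -0.63 ± 0.13. Gsdmc2, a gasdermin of the colonic epithelium, had -1.02 ± 0.32, or 2.03-fold. The Y-linked Eif2s3y had -0.60 ± 0.14 and the imprinted gene Nnat -0.62 ± 0.19. Tmem181c-ps had -0.79 ± 0.18 and Clca4c-ps -0.78 ± 0.19. Tuba1c (-0.70 ± 0.093), Speer4b (-0.69 ± 0.11), Zfp932 (-0.999 ± 0.18) and the mitochondrial factor Tfb2m (-0.65 ± 0.17) were dim. Again the adjusted p was 0.837 throughout. Nnat had -0.27 without the first and -0.96 without the second Mthfd1S+/- mouse, and Tfb2m -0.38 without the second. Oas1g, Gsdmc2, Tuba1c, Speer4b and both pseudogenes have close relatives whose transcripts the same probes may read.

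**Figure D1:**
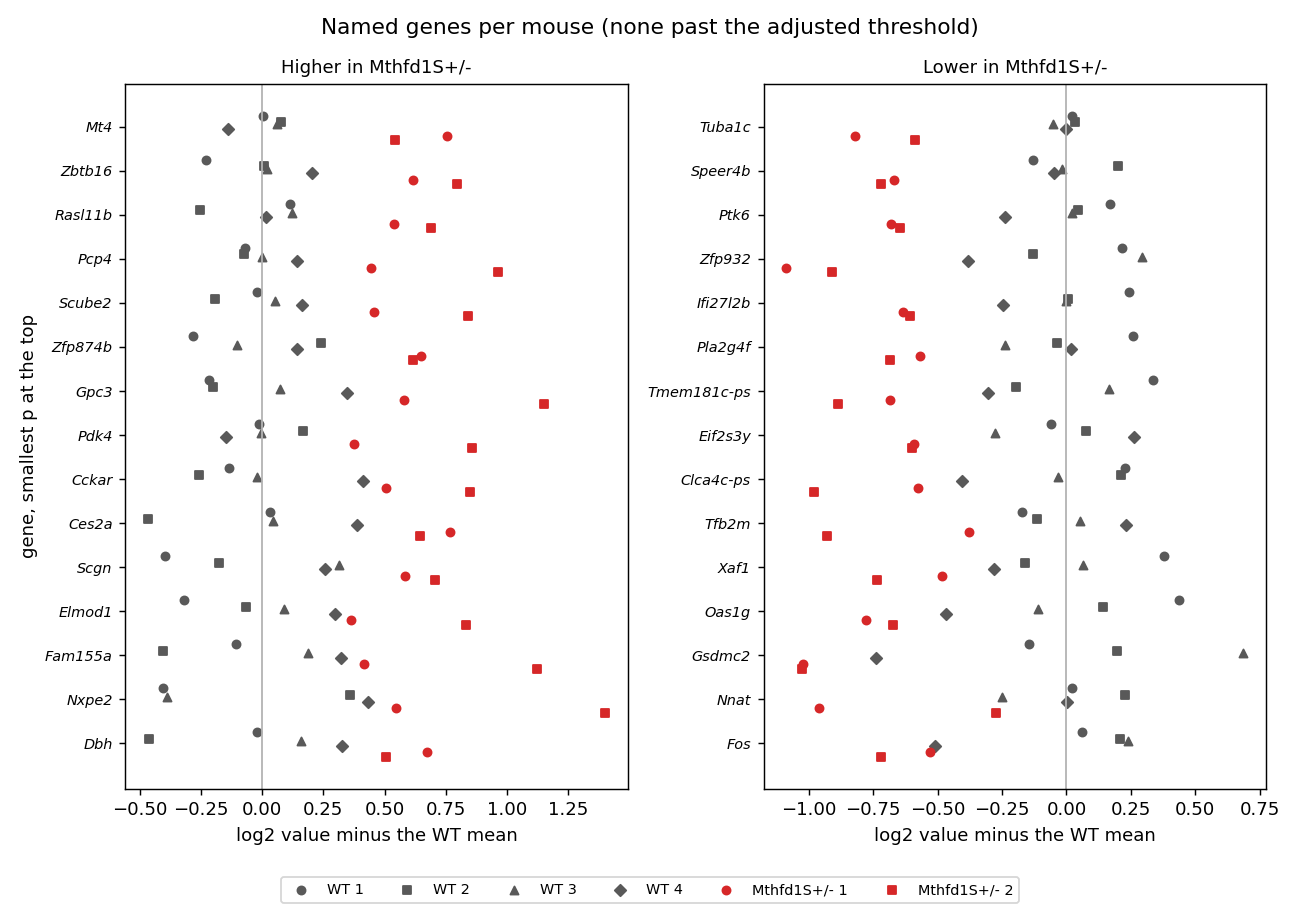
Log2 value of each named gene in each mouse minus the WT mean of that gene (horizontal axis), with 15 genes higher (left) and 15 lower (right) in Mthfd1S+/- mice; grey symbols are the 4 WT mice and red symbols the 2 Mthfd1S+/- mice. The groups do not overlap because the naming rule asks for it, and the adjusted p is 0.837 for each gene shown.

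Genes of folate-dependent one-carbon metabolism did not pass as a list: of 27 measured, 14 were higher and 13 lower in Mthfd1S+/- mucosa, with 0 at an unadjusted p under 0.05. List means were 0.086 and -0.096 in the 2 Mthfd1S+/- mice, on opposite sides of the -0.029 to 0.028 of the 4 WT mice. The largest value was that of Mthfd1l, the mitochondrial synthetase, at -0.32 ± 0.21 (SE). The mitochondrial dehydrogenase gene Mthfd2 had -0.15 ± 0.099 and Ggh, which trims folate polyglutamates, -0.18 ± 0.13. Positive values were those of the folate carrier Slc19a1 (0.16 ± 0.13), Mtrr (0.11 ± 0.080), Fpgs (0.11 ± 0.083) and Amt (0.12 ± 0.10). Shmt2 had 0.088 ± 0.12, Shmt1 -0.099 ± 0.13 and Aldh1l1 -0.16 ± 0.19, while the thymidylate synthase Tyms had -0.037 ± 0.15 and the purine enzymes Gart and Atic 0.056 ± 0.10 and 0.034 ± 0.12. The 95% interval included 0 for all 27. Camera gave the list an adjusted p of 0.863; 0 members passed when adjusted over the list alone and 0 over all genes.

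**Figure D2:**
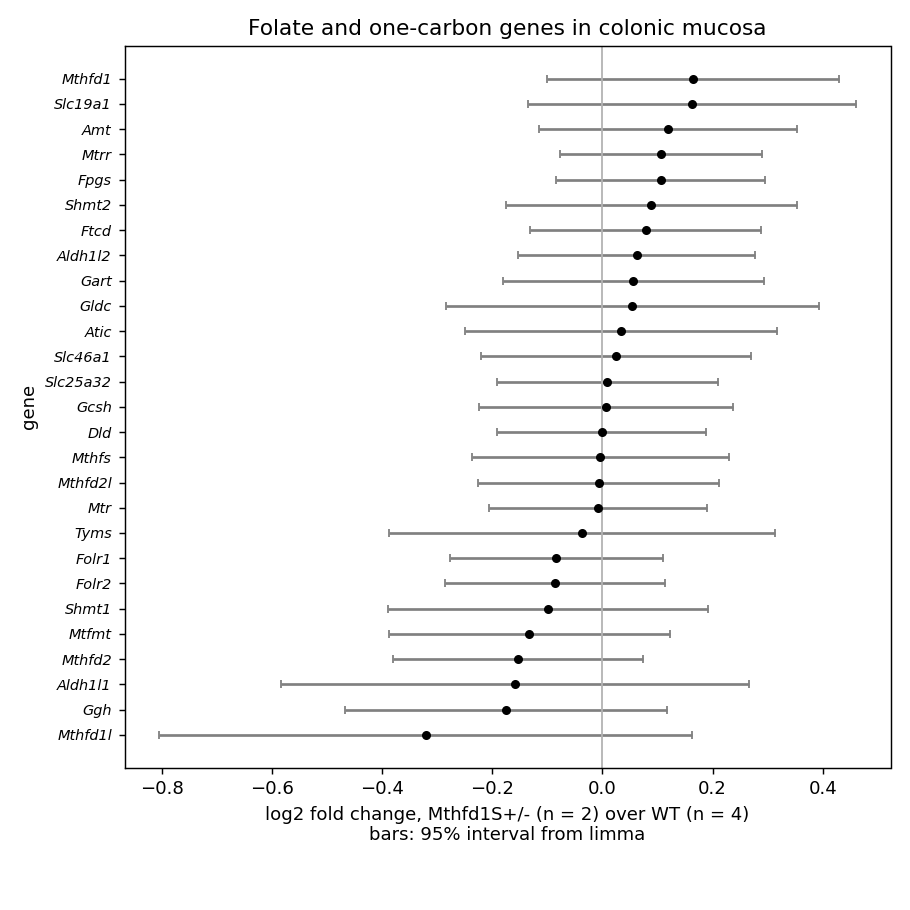
Log2 fold change of each of 27 folate and one-carbon genes, Mthfd1S+/- (n = 2) over WT (n = 4), on the horizontal axis; bars are 95% intervals from limma. The values run from -0.32 for Mthfd1l to 0.17 for Mthfd1, and each interval includes 0.

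Pathways next to folate were near 0 as well; number of genes, median log2 fold change and camera adjusted p are given in that order here and for other lists that did not pass. Purine synthesis (16 genes, median log2 fold change 0.029, adjusted p 0.866), pyrimidine and thymidylate synthesis (19 genes, 0.00024, 0.918) and DNA and histone methylation enzymes (18 genes, -0.020, 0.866) did not pass. Neither did serine and glycine synthesis (18 genes, 0.022, 0.777), the methionine cycle and transsulfuration (17 genes, 0.029, 0.650) or choline and betaine metabolism (17 genes, -0.013, 0.657). Single members at an unadjusted p under 0.05 were Mtap, which salvages methionine (0.24 ± 0.097), and the betaine aldehyde dehydrogenase Aldh7a1 (0.26 ± 0.099). In each of these lists 0 members passed when adjusted over the list alone and 0 over all genes.

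Across the 43 lists, camera with the preset correlation called 11, of which 6 were higher and 5 lower in Mthfd1S+/- mucosa. None held with an estimated correlation, where each of the 11 had an adjusted p of 0.902, and fry called 0 in one direction (smallest adjusted p 0.714) and 0 in either direction (0.167). The account of each called list states this p again, and 0 members of any list passed over all genes.

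Interferon-stimulated genes were lower in Mthfd1S+/- mucosa: 28 of 30 were lower, with a median log2 fold change of -0.23 and a camera adjusted p of 3.74e-08 (adjusted p = 0.90 with an estimated correlation). Zbp1, a nucleic acid sensor, had -0.53 ± 0.14 (SE), Oas3 -0.51 ± 0.17 and the ubiquitin-like Isg15 -0.60 ± 0.22. At an unadjusted p under 0.05 were 7 members, 0 passed when adjusted over the list alone and 0 over all genes. Mean levels of the list, with each gene centred over the 6 mice, were 0.34, 0.063, 0.18 and -0.21 in WT mice 1 to 4 and -0.15 and -0.22 in the Mthfd1S+/- mice, so WT mouse 4 lay between the latter. Without the second Mthfd1S+/- mouse the median was -0.14 and the list was still called. With the smooth muscle mean as a covariate the median was -0.048 (adjusted p 0.0226), and with the mean of the unnamed rows -0.12 (0.0406).

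Other immune lists did not pass. T and NK cell markers had a median log2 fold change of -0.048 (adjusted p 0.210) with the regulatory T cell factor Foxp3 at -0.30 ± 0.10 (SE). B and plasma cell markers had -0.057 (0.234), with Tnfrsf17 at -0.44 ± 0.13 and Mzb1 at -0.38 ± 0.14, both of plasma cells. Medians were 0.043 for macrophages and dendritic cells (0.951), 0.076 for neutrophils (0.777), -0.019 for MHC class II genes (0.464) and -4.7e-05 for inflammatory cytokines (0.621). Mast cell and eosinophil markers had 0.028 (0.712); 1 member, the mast cell protease Mcpt4, passed when adjusted over the list alone (0.0180) and 0 over all genes, at -0.56 ± 0.11 and a level near 3. Without WT mouse 2 the T and NK cell list was called lower (-0.082, 0.0215), and without the second Mthfd1S+/- mouse the neutrophil list was called higher (0.15, 0.0118). The smooth muscle covariate gave calls for neutrophils (0.15, 0.0139) and MHC class II genes (-0.16, 0.00958). The covariate of the unnamed rows gave calls for T and NK cells (-0.12, 0.0118), B and plasma cells (-0.15, 0.00717) and macrophages and dendritic cells (-0.12, 0.0118).

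Markers of muscle, nerve and connective tissue were higher in Mthfd1S+/- mucosa. All 16 smooth muscle markers were higher (median 0.25, camera adjusted p 5.46e-06; adjusted p = 0.90 with an estimated correlation), such as Casq2 at 0.59 ± 0.23 (SE) and the myosin kinase Mylk at 0.30 ± 0.13. Pcp4 alone passed when adjusted over the list alone (0.0165), and 0 over all genes. Of the enteric neuron and glia markers, 14 of 16 were higher (median 0.21, adjusted p 0.00182; adjusted p = 0.90 with an estimated correlation), including peripherin, Prph (0.57 ± 0.23), Nos1 (0.36 ± 0.15) and Gfap (0.30 ± 0.12). Of the fibroblast markers, 17 of 18 were higher (median 0.14, 0.00195; adjusted p = 0.90 with an estimated correlation), including Mfap4 (0.58 ± 0.23), Lum (0.42 ± 0.18) and Sfrp1 (0.32 ± 0.13). In both these lists 0 members passed when adjusted over the list alone and 0 over all genes. Without the second Mthfd1S+/- mouse the values were 0.25 for Casq2, 0.094 for Mylk, 0.35 for Prph, 0.21 for Nos1 and 0.19 for Sfrp1, and without the first 0.93 for Casq2 and 0.497 for Mylk.

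These 3 lists moved together across mice. Smooth muscle means were -0.19, -0.24, -0.020 and 0.083 in WT mice 1 to 4, and -0.040 and 0.41 in the Mthfd1S+/- mice. Without the second Mthfd1S+/- mouse, the medians were 0.022 for smooth muscle (adjusted p 0.806), 0.063 for neurons and glia (0.761) and 0.095 for fibroblasts (0.455). Without the first they were 0.45, 0.33 and 0.21. Without WT mouse 2 the neuron and fibroblast medians were 0.13 and 0.087, and without WT mouse 3 the fibroblast median was 0.22. With the smooth muscle mean as a covariate the neuron and fibroblast medians were -0.041 and 0.0037 and both calls were lost. With the mean of the unnamed rows as a covariate the 3 medians were 0.16 (still called, 0.0118), 0.048 and -0.010 (both lost). With the smooth muscle covariate 127 clusters were past p and 1.5-fold, with 24 of the main fit's 79 among them. With the unnamed rows covariate there were 214, with 27 of the 79, so this loss was not particular to muscle.

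Enteroendocrine markers, of the hormone-producing cells, were higher in 17 of 17 (median 0.19, camera adjusted p 4.31e-05; adjusted p = 0.90 with an estimated correlation). Cpe, which processes prohormones, had 0.60 ± 0.21 (SE), the transcription factor Neurod1 0.36 ± 0.17, the hormone Pyy 0.20 ± 0.095 and the granin Chgb 0.34 ± 0.17. Cpe had 0.33 and Chgb 0.21 without the second Mthfd1S+/- mouse, and Neurod1 had 0.21 without the first and 0.23 without WT mouse 1. When adjusted over the list alone 0 passed, and 0 over all genes. Without the second Mthfd1S+/- mouse the enteroendocrine median was 0.15, where that of the smooth muscle list was 0.022. With the smooth muscle mean as a covariate the enteroendocrine median was 0.055 and the call was lost (0.281). The call was also lost with the mean of the unnamed rows as a covariate (0.091, 0.304).

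Goblet cell markers were lower in 13 of 15 (median -0.027, mean -0.16, camera adjusted p 0.0372; adjusted p = 0.90 with an estimated correlation). Spink4 had -0.31 ± 0.10 (SE) and Retnlb, a secreted defence protein, -1.15 ± 0.59 (-0.70 without the first Mthfd1S+/- mouse); 0 passed when adjusted over the list alone and 0 over all genes. The median was 0.042 without the first Mthfd1S+/- mouse (0.818) and -0.20 without the second, -0.075 and -0.063 without WT mice 1 and 2, and the call was also lost without WT mouse 3 (0.137) or 4 (0.103). It was lost as well when arrays were quantile normalized again (0.146), over all rows (0.222) and with the other cluster per gene (0.0804). The same held with the replicate number as a block (0.226), and with the identifier letter (0.304) or the unnamed rows (0.177) as a covariate. With the smooth muscle covariate the median was -0.19 (2.48e-06), and with median-centred arrays -0.055 (0.0436). Absorptive colonocytes (22 genes, median -0.011, adjusted p 0.712), deep crypt secretory cells (7 genes, 0.049, 0.793), tuft cells (11 genes, -0.0088, 0.918) and squamous epithelium (15 genes, 0.0070, 0.754) did not pass. Epithelial antimicrobial genes had a median of -0.035 (18 genes, 0.182). They were called lower without WT mouse 4 (-0.14, 0.0286) and with the replicate number as a block (-0.26, 1.09e-05). Tuft cells were called lower with the smooth muscle covariate (-0.072, 0.00958). The colonocyte gene Clca4a had -0.52 ± 0.20. In these 5 lists 0 members passed when adjusted over the list alone and 0 over all genes.

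Adipocyte markers were lower in 8 of 11 (median -0.35, camera adjusted p 0.0406; adjusted p = 0.90 with an estimated correlation), with Car3 at -2.13 ± 0.93 (SE), the adipokine Adipoq at -0.91 ± 0.40 and Plin1 at -0.35 ± 0.15, while Cidea had 0.38 ± 0.13. Adipoq had -0.55 without WT mouse 3, and Plin1 -0.54 without the first and -0.16 without the second Mthfd1S+/- mouse. WT mouse 3 had a list mean of 0.84 against 0.21, -0.097 and -0.28 in the other WT mice and -0.36 and -0.31 in the Mthfd1S+/- mice. The call was lost without WT mouse 3 (median -0.22, 0.171), the first (-0.44, 0.103) or the second (-0.16, 0.280) Mthfd1S+/- mouse. It was also lost when arrays were quantile normalized again (0.0668) or median-centred (0.0749), over all rows (0.222), with the identifier letter (0.137) or smooth muscle (-0.17, 0.120) as a covariate, and with the other cluster per gene (0.0613). When adjusted over the list alone 0 passed, and 0 over all genes. Endothelial markers had a median of 0.020 (16 genes, 0.353), also with 0 and 0, and were called higher without WT mouse 3 (0.085, 0.0231).

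Intestinal stem cell and Wnt target genes were higher in 20 of 27 (median 0.13, camera adjusted p 0.00149; adjusted p = 0.90 with an estimated correlation). The Wnt antagonist Nkd1 had 0.47 ± 0.11 (SE), the transcription factor Prox1 0.40 ± 0.11, and the stem cell genes Smoc2 and Lrig1 0.38 ± 0.13 and 0.25 ± 0.084. At an unadjusted p under 0.05 were 7 higher and 2 lower members; 0 passed when adjusted over the list alone and 0 over all genes. List means were -0.098, -0.067, -0.040 and 0.0013 in WT mice 1 to 4 and 0.16 and 0.041 in the Mthfd1S+/- mice. Without the first Mthfd1S+/- mouse the median was 0.098 and the call was lost (0.103), with Prox1 at 0.25 and Smoc2 at 0.20. The call was also lost with the mean of the unnamed rows as a covariate (0.064, 0.226), and without the dimmest clusters the median was 0.22 (6.09e-04). Genes known from AOM/DSS or Apc-driven tumours, which share 5 genes with this list, had a median of 0.15 (23 genes, 0.156), and the 18 not shared one of -0.022, with 8 of them higher. Nkd1 passed when adjusted over that list alone (0.0499), 0 over all genes. That list was called higher without WT mouse 1 (0.24, 0.0208), WT mouse 2 (0.19, 0.0401) or the second Mthfd1S+/- mouse (0.14, 0.0118), and with the smooth muscle (0.31, 2.68e-04) or unnamed rows (0.10, 0.00855) covariate. Cell cycle genes (32 genes, 0.042, 0.682) and genes of ribosome biogenesis (18 genes, 0.0014, 0.754) did not pass, with 0 members passing when adjusted over the list alone and 0 over all genes. The 2 Mthfd1S+/- mice differed in their cell cycle means, 0.16 and -0.10, against 0.15, 0.11, -0.12 and -0.21 in WT mice 1 to 4. Cell cycle genes were called higher without the second Mthfd1S+/- mouse (0.19, 0.00295) and with the smooth muscle (0.28, 8.18e-10) or unnamed rows (0.16, 0.00379) covariate.

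Genes of lipid oxidation and PPAR targets were higher in 17 of 20 (median 0.12, camera adjusted p 9.89e-04; adjusted p = 0.90 with an estimated correlation). Pdk4 passed when adjusted over the list alone (0.0488) and 0 over all genes, at 0.62 ± 0.14 (SE) and 0.37 without the second Mthfd1S+/- mouse. Acot2, a mitochondrial thioesterase, had 0.29 ± 0.10, the lipid droplet gene Plin2 0.26 ± 0.12 and the thiolase Acaa2 0.23 ± 0.11. List means were 0.093 and 0.096 in the Mthfd1S+/- mice and -0.096, -0.0069, -0.086 and 0.00036 in WT mice 1 to 4.

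Cholesterol synthesis genes were lower in 16 of 17 (median -0.25, camera adjusted p 1.84e-04; adjusted p = 0.90 with an estimated correlation), including Sqle at -0.39 ± 0.23 (SE), Hsd17b7 at -0.37 ± 0.22 and Pmvk at -0.32 ± 0.13. Without the first Mthfd1S+/- mouse these had -0.83, -0.74 and -0.57, and without the second 0.044, -0.0092 and -0.071. The second Mthfd1S+/- mouse had a list mean of -0.55, the first one of 0.24, above WT means of 0.21, -0.15, 0.12 and 0.12. Without the second the median was 0.16 (0.0393), and without the first it was -0.65. With the smooth muscle mean as a covariate the call was lost (0.0023, 0.920), and with the mean of the unnamed rows the median was -0.61. When adjusted over the list alone 0 passed, and 0 over all genes.

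Immediate early genes were lower in 16 of 23 (median -0.068, camera adjusted p 0.00202; adjusted p = 0.90 with an estimated correlation). Fosb had -0.52 ± 0.15 (SE), Atf3 -0.71 ± 0.21 and Klf4 -0.27 ± 0.093, beside Fos; 0 passed when adjusted over the list alone and 0 over all genes. Fosb and Atf3 each had -0.34 without the second Mthfd1S+/- mouse, and Atf3 had -1.08 without the first. The call was lost without WT mouse 3 (median -0.053, 0.0831) and over all rows (0.0513). The median was -0.16 (0.00855) with the unnamed rows covariate and -0.039 (0.00477) with the other cluster per gene. Heat shock genes were higher in 13 of 13 but did not pass (median 0.15, 0.139), with 0 and 0 members passing in those ways. They were called higher without WT mouse 2 (0.15, 0.00397) or the first Mthfd1S+/- mouse (0.37, 1.55e-04), and with the unnamed rows covariate (0.38, 1.30e-05).

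Among the lists on carcinogen handling and DNA damage, xenobiotic metabolism had a median of 0.045 (21 genes, adjusted p 0.451). The cytochrome Cyp2c55 passed when adjusted over that list alone (0.0310), 0 over all genes, at 0.57 ± 0.12 (SE), or 11.99 ± 0.18 (SD, n = 4) in WT and 12.56 ± 0.010 (SD, n = 2) in Mthfd1S+/- mucosa. DNA damage and p53 target genes had 0.024 (26 genes, 0.754); Sesn1, a stress-induced sestrin, passed over the list alone (0.0127), 0 over all genes, at 0.53 ± 0.096, and Gadd45b had 0.37 ± 0.11. Alkylation, mismatch and base excision repair genes (23 genes, 0.0014, 0.951), apoptosis genes (26 genes, 0.0096, 0.650), transcripts of the mitochondrial genome (10 genes, -0.041, 0.353), clock genes (17 genes, 0.034, 0.788), posterior Hox genes (19 genes, 0.00091, 0.940) and the genes beside Mthfd1 (31 genes, 0.030, 0.682) did not pass. Transcripts of the mitochondrial genome were called lower with the smooth muscle covariate (-0.086, 0.0485), and their median was -0.091 without the second Mthfd1S+/- mouse. Clock genes were called lower with the unnamed rows covariate (-0.36, 0.0476) but higher with the replicate number as a block (0.21, 0.00783). In these 6 lists 0 members passed when adjusted over the list alone and 0 over all genes. In 9 lists, none of them called, median, mean and camera's direction did not share a sign.

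**Figure D3:**
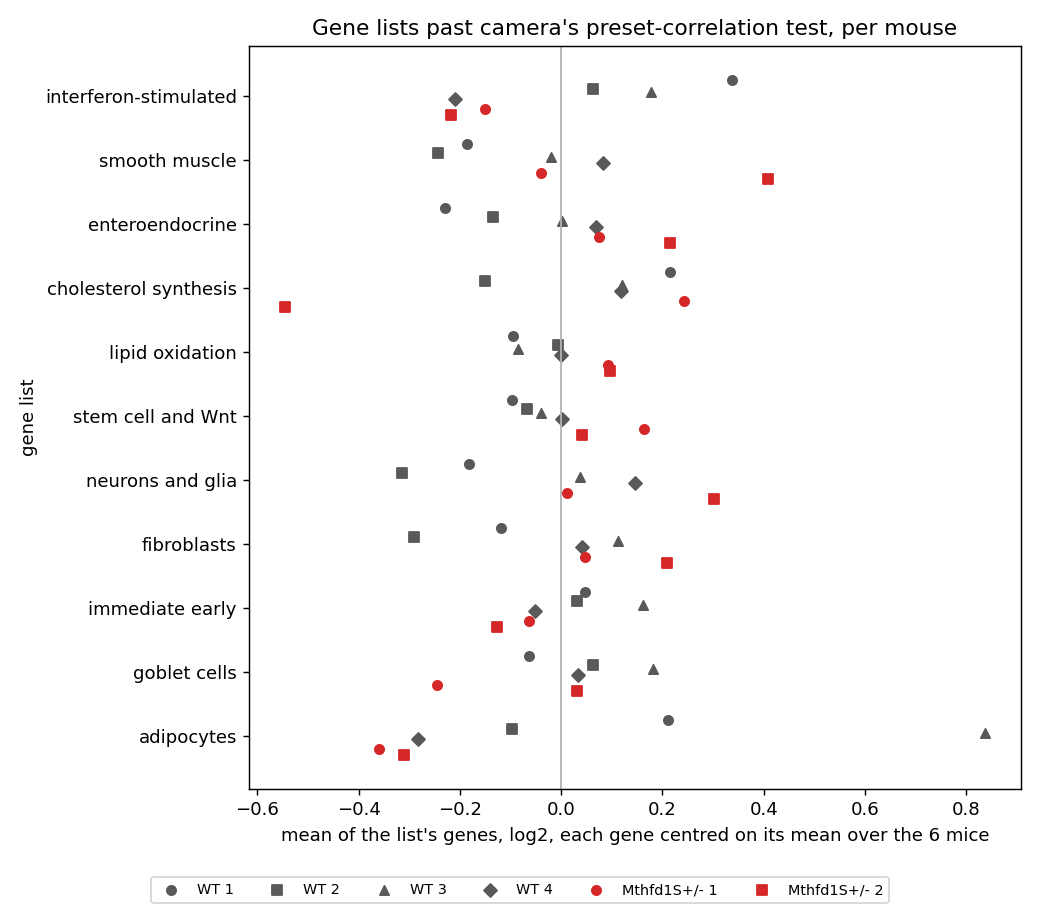
Mean log2 level of each of the 11 lists called by camera with the preset correlation, per mouse, with each gene centred on its mean over the 6 mice; grey symbols are the 4 WT and red symbols the 2 Mthfd1S+/- mice. For smooth muscle (0.41) and cholesterol synthesis (-0.55) the second Mthfd1S+/- mouse stands apart, and for adipocytes (0.84) WT mouse 3.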

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

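The tests of the interferon, muscle and Wnt patterns were chosen only after these patterns were seen, including the smooth muscle covariate, whose outcome was predicted before it was run. Of 142 values checked in the 4 WT mice for a mouse far from the others, 3 stood out, where chance gives 7.1. For Shmt1 the gap of WT mouse 2 (7.85 against 7.999, 8.01 and 8.01) was 0.908 of the group's range. For Acot2 the gap of WT mouse 4 (8.38 against 8.14, 8.13 and 8.12) was 0.922 of it. For the mean of the mitochondrially encoded transcripts the gap of WT mouse 1 (-0.052 against 0.038, 0.036 and 0.025) was 0.860 of it.

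Interferon-stimulated genes were lower in Mthfd1S+/- mucosa, with a median log2 fold change of -0.23 (adjusted p = 0.90 with an estimated correlation). Fewer immune cells stay open: the median of 76 immune markers was -0.019 (bootstrap 95% interval -0.069 to 0.023), and -0.045 and -0.013 without the first and the second Mthfd1S+/- mouse, but it was as low as that of the interferon list with the smooth muscle (-0.051 against -0.048) or unnamed rows (-0.122 against -0.117) covariate. A state that varies between mice whatever their genotype may account for it, since the lowest WT list mean (-0.209, mouse 4) lay below the higher Mthfd1S+/- one (-0.151). The 15 splits of the arrays are too few for a share under 0.05; 4 of them had a difference of the list mean at least as large in size as the real -0.277, the highest being 0.386. Smooth muscle content as a part of it and, untested, the genotype stay open, since the median was -0.048 (adjusted p 0.0226) with that content as a covariate, but -0.14 (3.12e-04) without the second Mthfd1S+/- mouse, where the smooth muscle median was 0.022 (0.806).

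Smooth muscle, neuron and fibroblast markers were higher in Mthfd1S+/- mucosa, mainly in the second mouse (adjusted p = 0.90 with an estimated correlation for each list, enteroendocrine markers included). A lower share of epithelium as the whole cause was tested on the enteroendocrine markers, which are epithelial and which that cause alone would lower. The test cannot decide it, since its bootstrap draws genes that move together (estimated correlation 0.40), not mice. The markers had a median of 0.195 (bootstrap 95% interval 0.1503 to 0.271), and 0.199 over the 7 hormone and endocrine factor genes alone. With the covariate for muscle content the medians were 0.055 (interval 0.015 to 0.153, camera adjusted p 0.281) and 0.102. With the unnamed rows covariate, which also ended the neuron and fibroblast calls, the first was 0.091 (-0.027 to 0.195). Without the second Mthfd1S+/- mouse the first was 0.153, where the smooth muscle median was 0.022. The covariate values thus do not show that muscle content alone set these markers. More gut wall muscle in some samples is a candidate explanation: with the smooth muscle mean as a covariate, the median of 34 neuron and fibroblast markers went from 0.176 to -0.012 (-0.068 to 0.075). That mean was highest in the second Mthfd1S+/- mouse (10.07, against 9.41 to 9.74 in the other mice), where the markers were mainly higher. Any covariate that follows this mouse could lower the median, so the test cannot single out muscle. Whether sampling depth or the genotype set that amount stays open, as an untested point.

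Stem cell and Wnt target genes were higher in both Mthfd1S+/- mice (adjusted p = 0.90 with an estimated correlation), with no call without the first of them (0.103) or with the unnamed rows covariate (0.226). Carry-over of tumour tissue cannot be told apart from other causes: 50 tumour-associated and cell cycle genes not on that list had a median of 0.031 (bootstrap 95% interval -0.016 to 0.090) against 0.126, but they split between the mice, and without the second Mthfd1S+/- mouse their median was 0.1500 (0.1099 to 0.211) against 0.178, and without the first -0.056 (-0.125 to 0.0025) against 0.098. Covariates gave medians of 0.249 (smooth muscle) and 0.127 (unnamed rows) against 0.129 and 0.064. The 15 splits are too few for a share under 0.05; the real difference of the list mean was 0.152, reached by 1 split, its own, and the highest other was 0.123 in size. The genotype stays open as an untested biological explanation.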

How the results depend on the processing

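The covariates for smooth muscle and unnamed rows were chosen after seeing the data. The number of clusters past the adjusted threshold was 0 under every alternative run, leave-one-out included. The count at an unadjusted p and 1.5-fold, 79, became 30 without variance moderation, 635 over all rows (92 higher), 129 with the letter of the mouse identifier as a covariate, 127 with the smooth muscle covariate, 214 with that of unnamed rows, 962 at 1.2-fold and 4 at 2-fold. Of the 635, 437 lower and 36 higher ones lay in the block of unnamed rows, and 90 in the other unnamed rows. These rows were absent from the main tests. Apart from these added rows and the fold thresholds, the cause was not tested. Leaving out 1 mouse gave 65 to 340. The Mthfd1 difference then ran from 0.0024 to 0.328 (p 0.985 to 0.0333 in limma), the latter without the second Mthfd1S+/- mouse. Called lists numbered 11, with 9 to 14 leaving out 1 WT mouse, and 0 with camera's estimated correlation and with fry. For camera, the correlation was the only setting changed. Its estimate in the 11 called lists ran from 0.044 (stem cell and Wnt) to 0.935 (cholesterol synthesis), above the preset 0.01. In simulated data with correlated members and no change, camera called a mean of 8.72 lists, and at least 11 in 26 of 100 data sets. Correlated members alone can thus give as many calls. For fry, the cause was not tested. Camera takes no robust or unmoderated variances, so these gave no list results.

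Leaving out 1 mouse, the adjusted p of camera ran from 2.64e-16 to 3.12e-04 for interferon-stimulated genes, 2.18e-13 to 0.806 for smooth muscle, 1.63e-05 to 0.761 for neurons, 1.04e-05 to 0.455 for fibroblasts, 7.62e-04 to 0.103 for the Wnt list, 3.90e-04 to 0.0831 for immediate early genes, 1.30e-04 to 0.818 for goblet cells and 0.00215 to 0.280 for adipocytes. Enteroendocrine and lipid oxidation lists were called each time, with at most 0.0472 and 0.0223.

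The titles number mice 1 and 2 in both genotypes. With the replicate number as a block, genotypes are compared only within mice 1 and 2, and the other WT mice add nothing to the difference. The counts were then 292 clusters and 14 lists. The block terms leave almost no residual degrees of freedom, so these counts and the calls that follow are weak. Newly called were cell cycle genes (-0.10, 0.00783), inflammatory cytokines (-0.027, 0.0122) and antimicrobial genes (-0.26, 1.09e-05) as lower, and clock genes as higher (0.21, 0.00783). Medians were 0.39 for neurons and glia, 0.29 for fibroblasts and 0.30 for enteroendocrine markers. Deviations correlated at 0.117 for pair 1 and -0.044 for pair 2, and with 2 Mthfd1S+/- mice their deviations mirror each other. These correlations cannot tell whether mice of equal number were paired, and the titles give no more than the shared number.

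Directions reversed in 8 cases. Leaving out 1 mouse, the goblet list's median ran from -0.198 to 0.042 and Atoh1 from -0.645 to 0.099, the highest without the first Mthfd1S+/- mouse. The cholesterol list ran from -0.650 to 0.155, Sqle from -0.833 to 0.044 and Sc5d from -0.428 to 0.022, the highest without the second. With the smooth muscle covariate camera's direction turned for neurons (-0.041) and fibroblasts (0.0037), and with the unnamed rows covariate for fibroblasts (-0.010). The cause was not tested. Of 855 other values of 72 named genes, without leave-one-out, 0 reversed. What the dim clusters show is limited by the background, which was not measured here.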

Other observations

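Chosen after the result was seen were the neighbour test and the account of the unnamed rows. The tests on glucocorticoid and FOXO targets and on Y-linked genes were chosen after the genes that prompted them were seen, but before the other genes of each test were, while those on the numbers of clusters and lists were planned. Several epithelial and defence genes, named here after their values were seen, spread more between mice than between genotypes. Clca4b, of absorptive cells, read 8.87, 8.57, 6.58 and 4.91 in WT mice 1 to 4 and 9.70 and 5.78 in the Mthfd1S+/- mice. Itln1, a secreted lectin, read 7.30, 8.23, 9.93 and 6.57 in WT and 6.55 and 6.62 in Mthfd1S+/- mice. The antimicrobial lectin Reg3b read 8.50, 8.93, 6.47 and 5.95 in WT and 7.60 and 7.31 in Mthfd1S+/- mice. Hspa1a, an inducible heat shock gene, stood at 10.97 in WT mouse 2 and 9.41 in the second Mthfd1S+/- mouse, against 7.66 to 8.58 in the other 4.

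A block of 5333 rows without a gene symbol, whose identifiers come before the first named one, was lower in Mthfd1S+/- mucosa in 3826 rows, with a median log2 fold change of -0.18. At an unadjusted p under 0.05 and 1.5-fold, 437 of them were lower and 36 higher, against 90 of the other 10677 unnamed rows. Array means were 4.99, 5.03, 4.83 and 4.81 in WT and 4.64 and 4.79 in Mthfd1S+/- mice, with an exact permutation p of 0.133. What these rows measure is not given in the sources used here.

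Zbtb16, Pdk4 and Sesn1 are known targets of glucocorticoid receptor or FOXO factors, and higher activity of these was tested as a hypothesis. Of 28 other targets 24 were higher, with a median log2 fold change of 0.129 (bootstrap 95% interval 0.081 to 0.186), against a median of 0.615 in those 3 genes. Camera gave p = 0.00229 with the preset correlation and p = 0.169 with an estimated correlation. The 3 genes were picked after their large changes were seen, so a lower median in the other targets does not argue against the hypothesis. A smaller common rise may exist, and the hypothesis stays open.

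Eif2s3y was lower, at -0.60 (95% interval -0.92 to -0.28), and lower expression of the Y chromosome's genes in general was tested as a hypothesis. Kdm5d had -0.17 (-0.42 to 0.083) and Uty -0.070 (-0.37 to 0.23), with a median of -0.119; a further gene planned for this test was not analysed here. The rule set beforehand asked, against the hypothesis, for a median of the planned genes above -0.298, a bound from the change of Eif2s3y. It also asked for no gene at an unadjusted p under 0.05. Kdm5d and Uty met both (limma p 0.162 and 0.603). Their intervals include 0, and that of Kdm5d also includes -0.298, a check outside that rule. With a planned gene missing, the hypothesis cannot be told apart from a change of Eif2s3y alone. DNA of another strain beside the mutated allele was tested on 30 neighbours of Mthfd1. Of these 2 were at an unadjusted p under 0.05, and the share of 10000 random lists with at least as many was 0.515. No excess of differing neighbours was thus seen. With 30 genes and 2 Mthfd1S+/- mice, a few real differences could not be told from chance, so the hypothesis stays open.

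The 15 splits of the 6 arrays are too few for a share under 0.05. For clusters past p and 1.5-fold, the real split gave 79, the highest other 152, and 3 splits at least as many. For called lists the real split gave 11, the highest other 17, and 7 splits at least as many.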
